A study of Mus musculus with 8 samples.

How the data were processed

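Expression values of 8 Affymetrix arrays were used, 1 per sample, from CCE mouse ES cells and embryoid bodies grown from them. The deposited values are on a log2 scale and were made with RMA, per the submitters' processing notes, which name no version and do not say which arrays were processed together. RMA corrects the background, normalizes arrays processed together to 1 distribution and summarises the probes of each probe set. Because the deposited columns fall into 3 sets of nearly equal distributions and not 1, they do not look as if all 8 arrays had been normalized in 1 run. Differences between sets can then hold a part that comes from the scaling, which affects the comparison of stages most. Biotin-labelled RNA was prepared from 1 microgram of total RNA with the manufacturer's one-cycle kit, per the labels.

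Of the probe sets, 64 array controls were set aside and 45037 remained. Gene symbols came from the platform annotation and were checked against a current gene table by gene number: 34945 probe sets had 1 symbol, 932 had several and 9160 had none, no symbol changed, and 204 kept the annotation's symbol for want of a match. A gene was represented by the probe set with the highest mean over the 8 arrays among those with exactly 1 symbol, which gave 18193 genes. Genes above the array's median over non-control probe sets in at least 2 arrays were tested, 12982 in all, and 5211 were left out as dim. Probes of near-identical genes may read each other's transcripts.

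One linear model was fitted to the 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior), with 4 states: embryoid bodies labelled Bmi1, vector embryoid bodies, ES cells labelled Bmi1, and control ES cells, which joined the untreated and the empty vector array. This left 4 residual degrees of freedom. The contrasts were labelled Bmi1 minus vector in embryoid bodies, labelled Bmi1 minus control in ES cells, the difference of these 2, and embryoid bodies minus ES cells in vector or control samples and in samples labelled Bmi1. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. An SE is that of the moderated fit.

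Before the data were examined, 20 gene lists were fixed for cell types, pathways and complexes, with 472 entries, of which 439 had a named probe set, 1 of them by a synonym, and 33 had none named here. They were tested with limma's camera with a preset correlation of 0.01, with camera with an estimated correlation and with fry, and adjusted over the lists of a contrast. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Some genes stand in 2 lists. Members were counted as called over all genes and adjusted over the list alone. Also fixed before the data were examined was the rule for the genes named: Bmi1, the 10 largest rises and 10 largest falls among called genes whose arrays do not overlap between groups for each of the 2 comparisons labelled Bmi1 against control, 5 in each direction for the others, and up to 4 members of each list with the smallest p. After the data were seen, the same rule was applied to the fit with the embryoid body set as a block, and genes so named are said to be.

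The replicate numbers in the labels were checked for pairing. Deviations from the group means over genes correlated at r = 0.72 between replicate 1 labelled Bmi1 and vector replicate 1 in embryoid bodies, and at 0.03 and 0.04 between these and ES cell replicate 1 labelled Bmi1. The first follows the sets seen in the distributions, so the set was treated as a batch of the 4 embryoid body arrays. The labels do not say whether these sets differ by processing, by culture or by both. A fit with a term for the set is given beside the results, with 3 residual degrees of freedom. It was chosen after the data were seen.

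Alternatives covered the filter on dim genes (none, or the 75th percentile), every probe set on its own, the mean of a gene's probe sets, quantile normalization of the 8 columns, median centring, a prior with intensity trend and robust estimation, array weights, arrays of 1 stage only, a minimum change of 2-fold, a replicate block over the 6 numbered arrays, either control ES cell array alone, and leaving out each array in turn. Where this left 1 array in a group, that array was assumed to vary like those of the other groups. The fits without 1 array had no block. Without 1 embryoid body array, an array of 1 set is compared with the mean of both sets. The result then takes up part of the difference between the sets and can leave the range of the values within the sets.

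Both fits were tested on simulated data for 12982 genes. The data were drawn from the blocked model, with the same spread of a gene on all arrays. This setting favours the blocked fit and lacks the wider spread of embryoid bodies, so it does not show which fit suits the real arrays. With 100 genes changed by 1 log2 unit and 100 by 2, the unblocked fit called 4% and 78% in embryoid bodies and 12% and 82% in ES cells, with no unchanged gene called. The blocked fit called 91% and 100% in embryoid bodies with 13 unchanged genes called, and 93% and 100% in ES cells with 18. Where 1 list was shifted and simulated genes varied independently, camera with the preset correlation called that list and none of the 19 others. This does not show how often camera calls a list falsely in these data, where the estimated correlation reached 0.90 for pluripotency genes. Array controls were read as signs of RNA quality and of background, and those for the transferrin receptor also as a second reading of that gene. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.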

Results

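Gene expression was measured on 8 Affymetrix arrays from CCE cells, a mouse embryonic stem (ES) cell line that grows undifferentiated with leukemia inhibitory factor. Per the labels, the cells were infected with a lentivirus that carried a mouse Bmi1 cDNA or with the empty vector, and eGFP-positive cells were sorted. Bmi1 is a core protein of Polycomb repressive complex 1, which keeps developmental genes silent. Total RNA came from ES cells and from embryoid bodies, the cell aggregates in which ES cells differentiate, harvested after 10 days. There were 2 arrays each of embryoid bodies labelled Bmi1, of embryoid bodies with the empty vector and of ES cells labelled Bmi1, and 1 array each of untreated and of empty vector ES cells, which together served as control ES cells. The series asks whether Bmi1 favours the formation of blood cells from ES cells. The small number of arrays limits the precision of every value, and since nothing in the labels says that replicates came from separate cultures, p-values measure the spread between these arrays, which may be technical.

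The arrays fell into 3 sets of nearly equal value distributions, namely the replicate 1 embryoid body arrays, the replicate 2 embryoid body arrays and the 4 ES cell arrays. The mean absolute difference between sorted values lay between 0.01 and 0.0323 log2 units for the 8 pairs of arrays within a set and between 0.189 and 0.442 for the 20 pairs across sets. Each embryoid body set held 1 array labelled Bmi1 and 1 vector array, so the main embryoid body results are also given with the set as a block or within each set. Each set held arrays of 1 stage, so small differences between stages cannot be told from differences between sets. Replicates lay further apart in embryoid bodies than in ES cells: the root mean square difference between the 2 arrays over all tested genes was 0.51 log2 units in embryoid bodies labelled Bmi1, 0.67 in vector embryoid bodies, 0.27 in ES cells labelled Bmi1 and 0.23 between the 2 control ES cell arrays. The main fit joins both stages in 1 spread per gene. Its SEs and p-values may thus be too small in embryoid bodies and too large in ES cells. For Bmi1 the SE was 0.37 at both stages in that fit. It was 0.41 from embryoid body arrays alone and 0.23 from ES cell arrays alone.

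The transduced gene was examined first, because it checks the labels. Bmi1 signal was lower in the arrays labelled Bmi1 than in their controls at both stages. With the brighter of its 2 probe sets it read 7.48 and 8.51 log2 units in embryoid bodies labelled Bmi1 against 9.35 and 9.67 in vector embryoid bodies, a log2 difference of -1.51 ± 0.37 (SE, n = 2 and 2 arrays). In ES cells labelled Bmi1 it read 5.68 and 6.28, against 7.41 in untreated and 7.74 in empty vector ES cells, a log2 difference of -1.59 ± 0.37 (SE, n = 2 and 2 arrays). The other Bmi1 probe set gave -1.59 in embryoid bodies and -1.58 in ES cells. By limma neither difference passed Benjamini-Hochberg adjustment over the 12982 genes tested, with adjusted p = 0.31 and 0.26, and both passed with the embryoid body set as a block, with adjusted p = 0.04 and 0.041. Within the sets the difference in embryoid bodies was -1.87 for the replicate 1 arrays and -1.15 for the replicate 2 arrays. Whether either probe set lies within the transduced cDNA is not given in the sources used here, and if both lie outside it these values do not check the labels. Since the signal goes against the labels, samples are called "labelled Bmi1" throughout, and every direction given is that of the arrays so labelled.

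**Figure D1:**
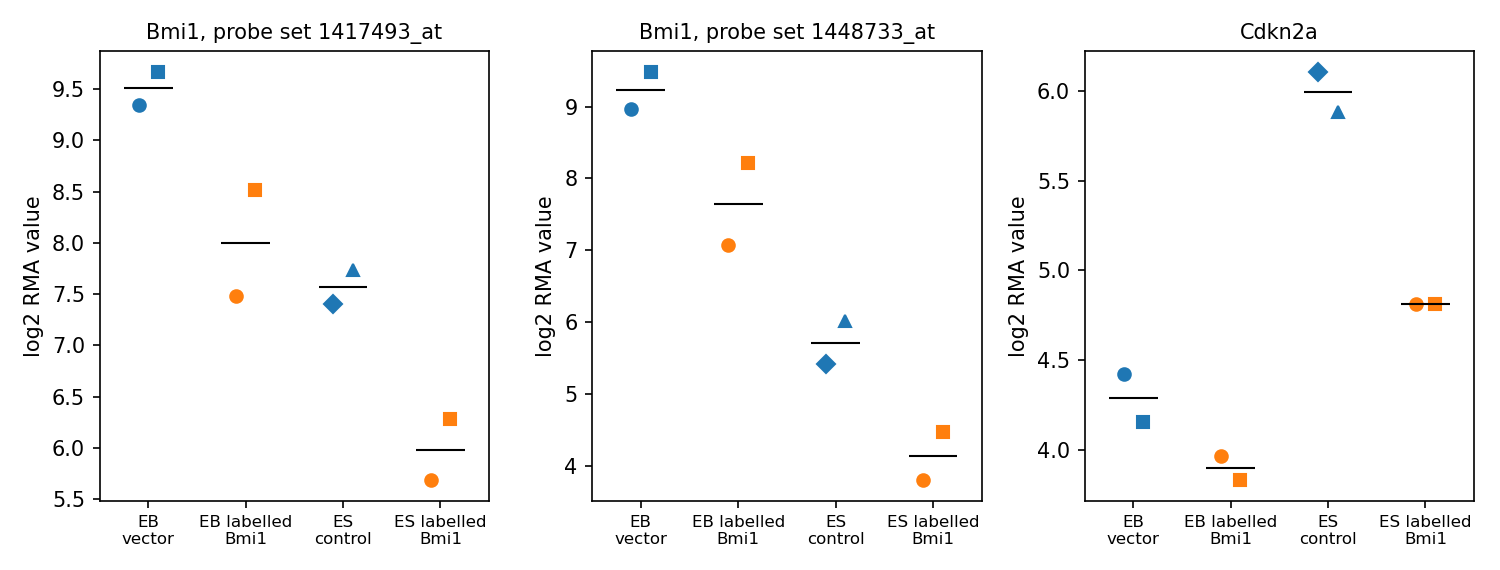
Signal of both Bmi1 probe sets and of Cdkn2a on each of the 8 arrays, on the log2 scale of the deposited values. Circles and squares are replicates 1 and 2, diamonds and triangles are the untreated and empty vector ES cells, and bars are group means. Bmi1 reads lower in each array labelled Bmi1 than in the controls of its stage, and Cdkn2a reads lower in the ES cells labelled Bmi1, with a log2 difference of -1.19.

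The first comparison asked how embryoid bodies labelled Bmi1 differed from vector embryoid bodies after 10 days. The largest rise was in Serpinb9g, a member of a cluster of intracellular serine protease inhibitors, with a log2 difference of 4.44 ± 0.54 (SE, n = 2 and 2 arrays, adjusted p = 0.048), and of 5.31 and 3.57 in the replicate 1 and 2 arrays. Its relative Serpinb9d rose by 2.08 ± 0.17, although probes of such closely related genes may read each other's transcripts. Also higher were 1700011M02Rik (2.98 ± 0.22), Plbd1, a phospholipase B domain protein (2.45 ± 0.21), Dmkn, a secreted epidermal protein (2.35 ± 0.27), and Pparg, the nuclear receptor that drives fat cell formation (2.29 ± 0.25). Slco4a1, an organic anion transporter (2.21 ± 0.18), Rassf6 (2.18 ± 0.26), Mlkl, the effector of necroptosis (2.07 ± 0.24), and Olr1, a receptor for oxidised low-density lipoprotein (1.92 ± 0.19), completed the 10 largest rises, and the 9 after Serpinb9g were at 1.83 to 3.15 in the replicate 1 and 1.63 to 2.80 in the replicate 2 arrays. Hoxa10, a homeobox gene of the posterior body and of blood progenitors, was the single gene that fell, by 1.57 ± 0.19 on the log2 scale (adjusted p = 0.047, and -1.78 and -1.37 in the sets). This call was lost without the filter on dim genes, with the 75th percentile filter, over every probe set and with the mean of probe sets. It was also lost after quantile normalization or median centring, with intensity trend and robust prior, with array weights and with embryoid body arrays alone. In all, limma called 18 of 12982 genes, 17 higher and 1 lower, but 0 when fitted to the embryoid body arrays alone. With the embryoid body set as a block, which was chosen after the data were seen, it called 271 genes, 175 higher and 96 lower, and all 18 were among them. Fits without 1 embryoid body array had no block and mix in the difference between the sets. The unblocked count was 218 without vector replicate 2, 12 without vector replicate 1 and 0 without any 1 of the other 6 arrays.

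Further genes passed only with the block, and their names were chosen by the same rule after the values were seen. Those higher in embryoid bodies labelled Bmi1 included Myh6, the alpha cardiac myosin heavy chain, at 3.47 (4.85 in replicate 1 and 2.10 in replicate 2 arrays), Fam90a1b at 3.08, Lonrf3 at 2.89, Gjb2, a connexin, at 2.83, 1600025M17Rik at 2.62, Ldoc1 at 2.51 and 3830417A13Rik at 2.49. After Myh6 these were at 3.27 to 4.15 in the replicate 1 and 1.65 to 2.31 in the replicate 2 arrays. Those lower included the neural markers Zic1 at -2.37 (-3.34 and -1.40 in the replicate 1 and 2 arrays, and -3.77 to -0.97 without 1 array) and Fabp7 at -1.89, and Cbln4 at -2.27 (-3.06 and -1.48). The embryonic globins Hba-x and Hbb-bh1, made by primitive red cells, were lower at -1.83 (-1.41 and -2.25, and -2.45 to -1.20 without 1 array) and -1.66 (-1.68 and -1.64, and -2.23 to -1.09 without 1 array). 2610528A11Rik at -1.62, Nrn1 at -1.59 (-2.02 and -1.16) and Scel at -1.49 followed, and another, dim probe set of Scel had the opposite sign, at 0.38.

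Interferon response genes rose together in embryoid bodies labelled Bmi1. All 16 measured members were higher in both embryoid body sets, with a median log2 difference of 1.39, and of 1.5 in the replicate 1 and 0.96 in the replicate 2 arrays. The list test (camera) gave adjusted p = 5.5e-23 with a preset correlation, and the call held with an estimated correlation, adjusted p = 0.016, and with the block, adjusted p = 3e-16, but not with both, adjusted p = 0.11. No member passed over all genes without the block, 12 passed with it, and 13 passed adjusted over the list alone. Ifih1, a cytoplasmic sensor of double-stranded RNA, was at 2.01 ± 0.28, Oasl2 at 1.90 ± 0.31, Rtp4 at 1.81 ± 0.23 and Usp18, a brake on interferon signalling, at 1.62 ± 0.27 (SE, n = 2 and 2 arrays each). Isg20 (1.63), Ifi35 (1.59) and Parp14 (1.29), singled out after their values were seen because they are also interferon-induced, were among the 18 called genes.

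Endothelial genes fell together. Their median log2 difference was -0.69 over 19 members, -0.77 in the replicate 1 and -0.59 in the replicate 2 arrays, with camera adjusted p = 3.4e-14, and adjusted p = 0.016 with an estimated correlation. With the block it was called at adjusted p = 2e-10, and not with block and estimated correlation together, adjusted p = 0.11. None passed over all genes without the block, 5 were called lower with it, and 11 were called lower adjusted over the list alone. Tek, the angiopoietin receptor, was at -1.09 ± 0.22, Emcn, an endothelial sialomucin, at -0.96 ± 0.18, Plvap at -0.88 ± 0.21 and Ramp2 at -0.76 ± 0.18 (SE, n = 2 and 2 arrays each).

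Blood cell lists, which bear on the question of the series, did not move as one. In the erythroid list 10 of 11 members were lower, with a median of -0.38 (-0.26 and -0.39 in the replicate 1 and 2 arrays). Its camera adjusted p was 0.0025, or 0.0038 with the block, but 0.12 with an estimated correlation and 0.074 without replicate 2 labelled Bmi1. Hba-x was at -1.83 ± 0.38, Hbb-bh1 at -1.66 ± 0.46 and Hbb-y at -1.40 ± 0.29, whereas Tfrc, the transferrin receptor, was at 1.30 ± 0.20 (SE, n = 2 and 2 arrays each). Hba-x, Hbb-bh1 and Tfrc were called with the block, and probes of the globin family may read more than 1 member. Among blood transcription factors Gata2 was at 1.43 ± 0.22 and Lyl1 and Lmo2 at -0.75 ± 0.16 and -0.82 ± 0.22. Without 1 array Lmo2 ran from -1.11 to -0.53. Gata2 and Lyl1 were called with the block, and the list, with a median of -0.23, was not called by camera, adjusted p = 0.083, but was called lower by fry, adjusted p = 0.047, and by camera without replicate 1 labelled Bmi1 (0.016) or vector replicate 2 (0.048).

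The lists of general blood cell genes and of macrophage and granulocyte genes had medians of -0.25 and -0.38, with adjusted p = 0.15 and 0.17, and their medians had opposite signs in the 2 embryoid body sets. They were -0.91 and -0.998 in the replicate 1 arrays and 0.32 and 0.36 in the replicate 2 arrays. Without vector replicate 1 the list means were 0.47 and 0.64, and without vector replicate 2 they were -0.89 and -1.14. Without replicate 1 labelled Bmi1 they were -0.29 and -0.39. These fits set 1 array against the mean of both sets, so these means hold part of the difference between the sets. No member of either was called with or without the block, including Kit at -0.73, the stem cell factor receptor, and Cd68 at -0.47. The megakaryocyte and mast cell list had a median of -0.01 and adjusted p = 0.92, with medians of -0.25 and 0.22 in the replicate 1 and 2 arrays, and it was called higher without vector replicate 1 (adjusted p = 0.04).

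Trophoblast genes were higher in 12 of 12 members, with a median log2 difference of 1.16 (1.61 and 0.67 in the replicate 1 and 2 arrays) and camera adjusted p = 2.1e-11, or 1.2e-08 with the block, but adjusted p = 0.12 with an estimated correlation. The placental genes Plac1 at 1.49 ± 0.26 and Peg10 at 1.26 ± 0.33 were called with the block, and 6 of 12 members were called adjusted over the list alone. Rhox6 and Rhox9, near-identical neighbours whose probes may not tell them apart, were at 2.40 ± 0.48 and 2.36 ± 0.45. Hox genes were lower in 15 of 18 members, with a median of -0.30 (-0.42 and -0.29 in the sets) and adjusted p = 1.6e-06, or 2.7e-05 with the block, and adjusted p = 0.22 with an estimated correlation and 0.074 without replicate 2 labelled Bmi1. Hoxa10 passed over all genes in the main fit, a call lost in most other unblocked settings, as said above. Hoxd10 and Hoxa11, at -1.21 ± 0.23 and -1.21 ± 0.26, were called with the block. Cardiac muscle genes had a median of 0.50 (0.90 and 0.15 in the sets), with adjusted p = 3e-04, or 5.2e-04 with the block, and adjusted p = 0.32 with an estimated correlation. Pln, a regulator of the cardiac calcium pump, rose by 1.80 ± 0.18, and Gata4 was at -1.04 ± 0.28.

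Of the remaining lists, neuroectoderm genes had a median of -0.43 (-0.21 and -0.55 in the sets) and adjusted p = 0.018, or 0.0044 with the block, but adjusted p = 0.22 with an estimated correlation, and the call was lost without replicate 2 labelled Bmi1 (0.11) or vector replicate 2 (0.26). Visceral and definitive endoderm genes had a median of -0.35 and adjusted p = 0.016, with medians of -0.0031 and -0.61 in the replicate 1 and 2 arrays, so no fall in the former, and adjusted p = 0.39 with an estimated correlation and 0.10 with the block, and the call was lost without replicate 2 labelled Bmi1 (0.75) or vector replicate 2 (0.30). The lists for Polycomb complexes (median 0.03), imprinted genes (-0.16), pluripotency (-0.15), early mesoderm (-0.17), mesenchyme (-0.12), cell cycle inhibitors (-0.22), proliferation (0.06) and hypoxia and glycolysis (-0.23) were not called, with adjusted p between 0.13 and 0.95. Leaving out 1 embryoid body array mixes in the difference between the sets. In such fits early mesoderm genes were called lower without replicate 1 labelled Bmi1, and proliferation genes higher without that array or vector replicate 2. Cell cycle inhibitors were called lower without vector replicate 1, and hypoxia genes lower without vector replicate 2. Pluripotency and mesenchyme genes had medians of opposite sign in the replicate 1 and 2 arrays, 0.27 and -0.55 and -0.52 and 0.29. They also went in opposite directions without 1 or the other vector array. Cdkn2a, the Ink4a/Arf locus that Bmi1 is known to repress, was at -0.39 ± 0.18 and Cdkn2b at -0.70 ± 0.18 in embryoid bodies, and neither passed with or without the block.

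**Figure D2:**
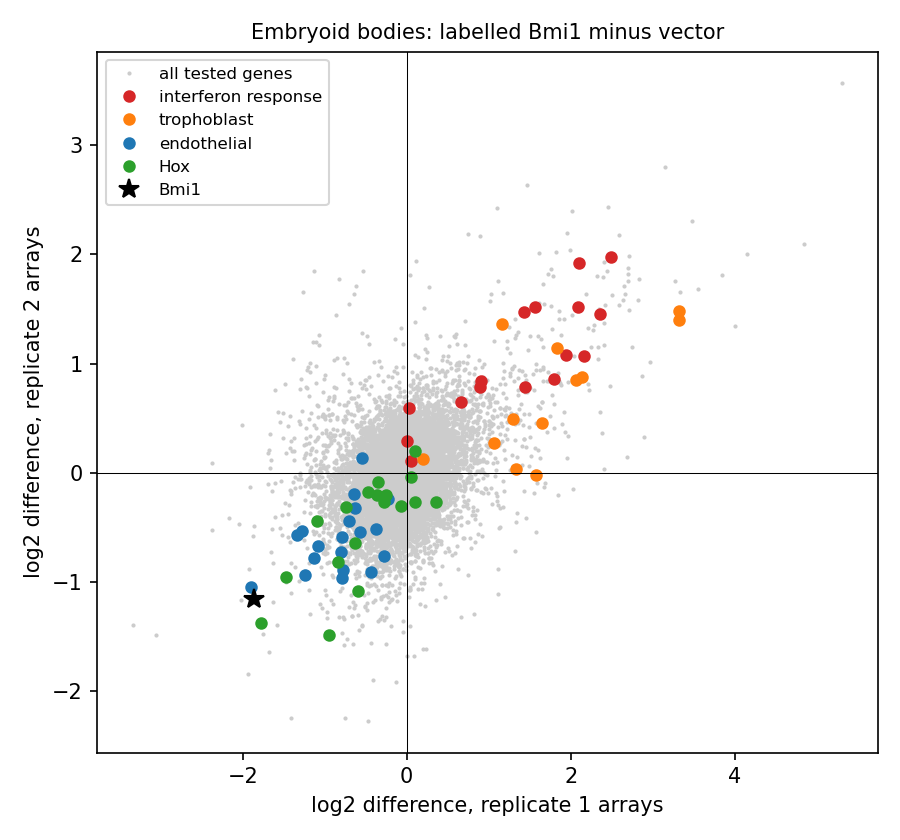
Log2 difference between embryoid bodies labelled Bmi1 and vector embryoid bodies for each tested gene, in the replicate 1 arrays (horizontal) and the replicate 2 arrays (vertical). The 16 interferon response genes lie above 0 on both axes, the endothelial genes below 0 in the replicate 1 arrays, and Bmi1 at -1.87 and -1.15.

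The second comparison asked how ES cells labelled Bmi1 differed from control ES cells before differentiation. There 6 genes rose and none fell: Hmgn3, a nucleosome-binding protein, by 2.83 ± 0.25 (SE, n = 2 and 2 arrays, adjusted p = 0.037), Slc25a24, a mitochondrial carrier (2.51 ± 0.22), Pogk (2.31 ± 0.22), Cdk14, a cyclin-dependent kinase (1.88 ± 0.19), St6gal2, a sialyltransferase (1.77 ± 0.16), and App, the amyloid precursor protein (1.72 ± 0.17). Another bright probe set of App rose by 1.5, and the 2 dim ones were at -0.01 and 0.14. The dimmer probe sets of Cdk14 were at 0.05 and 0.19, and that of Pogk at 0.63. With the embryoid body set as a block, which leaves these differences as they are and lowers the shared estimate of the spread, 216 genes were called, 181 higher and 35 lower, and the 6 were among them. The unblocked count was 50 without either vector embryoid body array and 0 without any 1 of the other 6 arrays, and it was 0 against the empty vector array alone and against the untreated array alone.

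Genes called in ES cells only with the block, and named after the values were seen, included the germ cell genes Tex11 (3.83) and Rbm46 (2.64), Nefm, a neurofilament (3.03), Tagln, a smooth muscle protein (2.56), Rhox5 (2.56), Sema3c (2.45), Ptgs2, the inducible cyclooxygenase (2.37), and Gatm (2.32) among those higher. Lower were Igf2bp3, an RNA-binding protein (-3.26), Tenm3 (-2.10), Mllt10 (-1.97), Ttn (-1.58), Ccnd2 (-1.38), Morc1 (-1.32), Add3 (-1.29), Cdkn2a (-1.19, blocked adjusted p = 0.017) and Pura (-1.16). The other bright probe set of Ttn fell too, at -0.98, while 2 dim ones lay just above 0, at 0.10 and 0.01. Of the 5 other probe sets of Pura 4 fell, by 1.06 to 1.83, and a dim one was at 0.03. The other probe sets of Add3 were at -1.13, -1.40 and -0.16, the last of them not dim.

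Imprinted genes were the list with the smallest p in ES cells. They were higher in 17 of 21 members, with a median of 0.46 and camera adjusted p = 2.2e-08, and adjusted p = 0.052 with an estimated correlation. Nnat (1.42 ± 0.16), Ndn (0.97 ± 0.22, with a dim probe set at -0.10) and Grb10 (1.57) were called with the block, Grb10 being named after its value was seen, and 6 members were called adjusted over the list alone. Dlk1, a Notch pathway ligand, was at 1.54 ± 0.32. Trophoblast genes had a median of 0.56 and adjusted p = 0.013, but adjusted p = 0.94 with an estimated correlation and 0.30 without ES cell replicate 2 labelled Bmi1. The interferon list had a median of -0.06 and adjusted p = 0.50, and Gbp2 at 1.80 was called with the block. Pluripotency genes had a median of -0.20 and adjusted p = 0.27, or adjusted p = 0.0081 with the block, which was lost with block and estimated correlation together, adjusted p = 0.84, and no member was called. The lists for endothelial (median 0.05), erythroid (0.05), blood transcription factors (0.04), general blood cell (-0.06), macrophage (-0.04), megakaryocyte (0.01), cardiac (-0.03), endoderm (-0.05), neuroectoderm (0.08), early mesoderm (-0.06), mesenchyme (0.05), Polycomb (-0.07), Hox (-0.03), cell cycle inhibitor (0.22), proliferation (-0.07) and hypoxia genes (0.00) were not called, with adjusted p between 0.14 and 0.92.

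**Figure D3:**
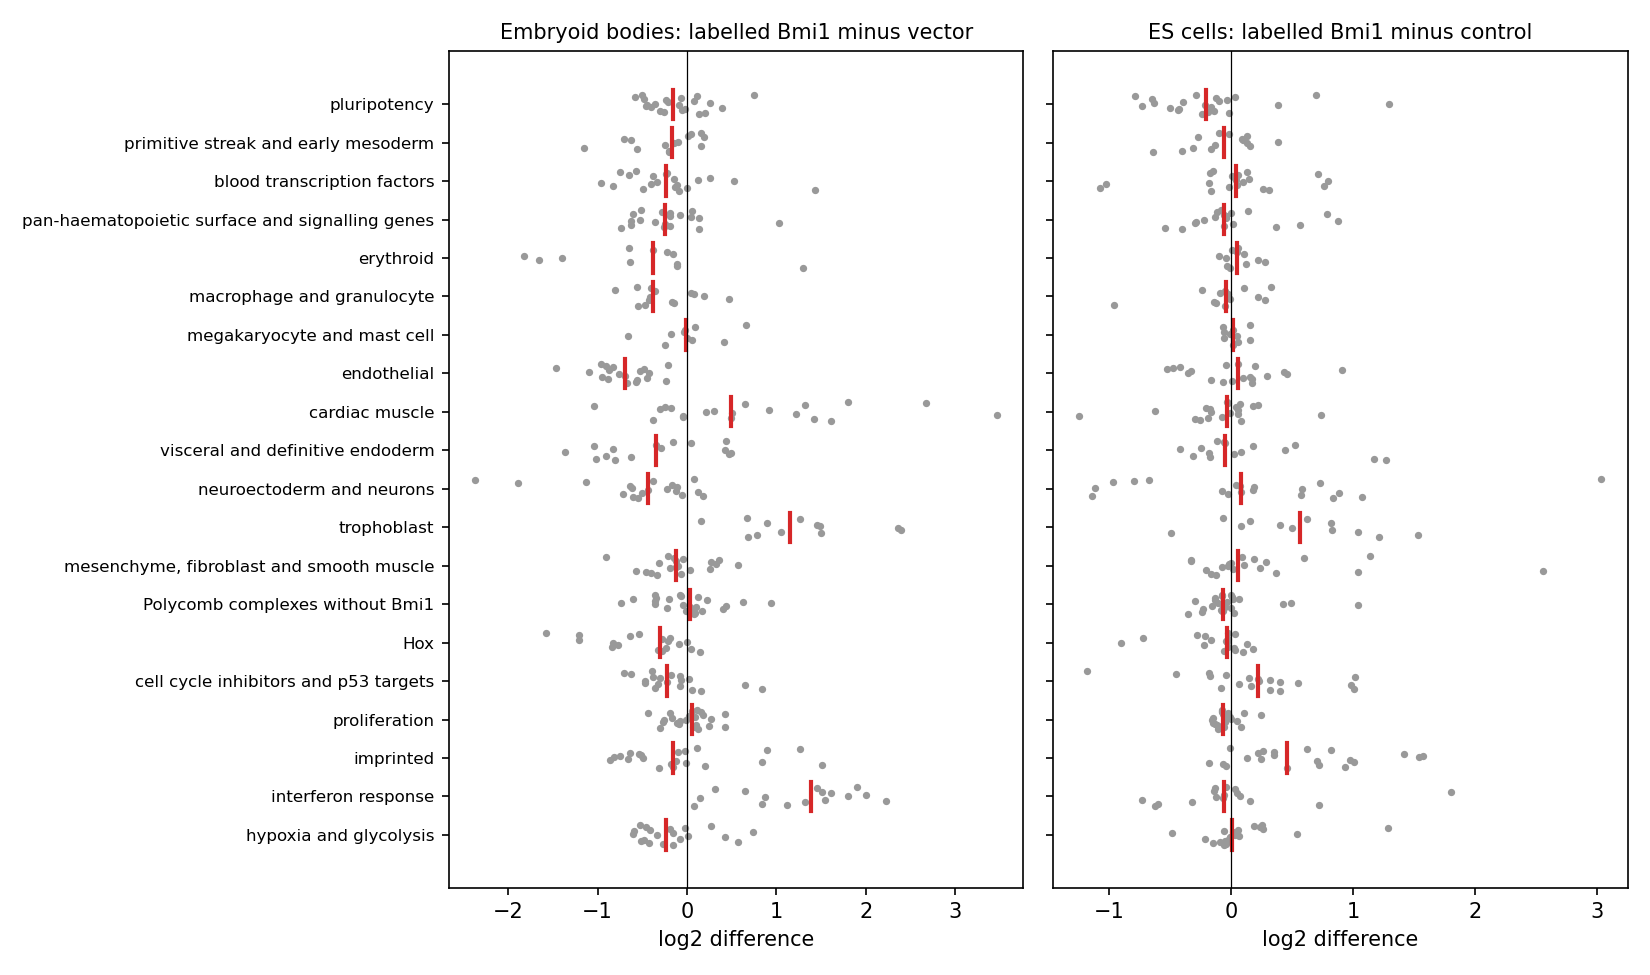
Log2 differences of the members of the 20 gene lists in embryoid bodies (left) and in ES cells (right). Grey points are genes and red lines are medians. In embryoid bodies the interferon list (median 1.39) and the trophoblast list (1.16) lie above 0 and the endothelial list (-0.69) lies below 0, and in ES cells the imprinted list has a median of 0.46.

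The third comparison asked whether the 2 effects differed. No gene passed for the difference between the effect in embryoid bodies and in ES cells, with limma's smallest adjusted p at 0.13 and 887 genes at an unadjusted p under 0.05. With the block 107 genes passed, 46 higher and 61 lower. The count was 100 without vector embryoid body replicate 2 and 1 without vector embryoid body replicate 1. Named after the values were seen, the difference was 4.46 for Serpinb9g, 2.86 for Gjb5, 2.83 for 1700011M02Rik, 2.69 for Ttn and 2.57 for Igf2bp3, and -2.98 for Igfbp3, -2.87 for Klhl4, -2.74 for Hmgn3, -2.62 for Fabp7 and -2.56 for Myl9. Across the 12982 genes, which are not independent replicates, the 2 effects had Pearson's r = 0.09 and Spearman's rho = 0.05, and the 2 comparisons share no arrays. With the block 7 genes were called higher in both, 2 lower in both, Bmi1 and Pura, and 3 in opposite directions. The calls share each gene's spread, so they are not independent and no expected number is given.

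The last comparisons described the change from ES cells to embryoid bodies. Stage goes with array set here, so small changes may come from the sets. The mean absolute difference between sorted values was at most 0.442 log2 units for a pair of arrays from different sets. Single sorted values differed by more. The largest changes given below are far beyond that mean. Signs of RNA quality differed with the stage as well. The 18S ribosomal RNA control probe sets averaged 13.71 and 13.44 log2 units in labelled Bmi1 and control ES cells against 7.70 and 7.19 in labelled Bmi1 and vector embryoid bodies, and the 3' minus 5' difference of the actin control was 0.44 and 0.40 against 0.85 and 0.73. For the transferrin receptor control it went the other way, at 2.40 and 2.52 against 2.08 and 1.72. For the Gapdh control it was 0.07 and 0.07 against -0.01 and 0.02. The 3' minus 5' differences thus do not show that RNA was poorer at either stage. In vector embryoid bodies against control ES cells, Col3a1, a fibrillar collagen (10.11 ± 0.29), Cdh11, a mesenchymal cadherin (9.36 ± 0.22), Afp, the alpha-fetoprotein of visceral endoderm (8.65 ± 0.29), Lum (8.29 ± 0.67) and the embryonic globin Hbb-y (8.04 ± 0.29) were the 5 largest log2 rises (SE, n = 2 and 2 arrays). Gbx2 (-6.56 ± 0.24), Pou5f1, a core factor of pluripotency (-5.07 ± 0.56), Hsf2 (-5.01 ± 0.21), Slc27a2 (-4.95 ± 0.45) and Nefh (-4.84 ± 0.32) fell most. All 22 pluripotency and all 23 proliferation genes were lower by value, and 20 of 20 mesenchyme, 19 of 20 cardiac, 18 of 19 endothelial, 16 of 18 Hox and 13 of 14 macrophage genes were higher. Their camera adjusted p ranged from 1.7e-09 to 3.3e-05, and with an estimated correlation none of the 20 lists was called, the smallest adjusted p being 0.09. In ES cells and embryoid bodies labelled Bmi1 the change ran in parallel, with 6614 genes called in both in the same direction and 7 in opposite directions, and r = 0.95 across genes. Both changes compare the same array sets and share each gene's spread, so part of this likeness may come from the sets and the fit. Col3a1 (10.04), Afp (9.10), Cdh11 (8.88), Lum (8.75) and Serpinb9g (8.39) were the 5 largest rises there, and Gbx2 (-5.86), Slc27a2 (-5.62), Nefh (-5.58), Pou5f1 (-5.30) and Hsf2 (-5.17) fell most. In ES cells these 6 rising genes read 2.70 (Afp) to 3.76 (Lum), near the 3.06 to 3.99 of the TrpnX array controls, so their signal there was at background, their changes are lower bounds and their order may be set by that floor. The same holds for the fall of Hsf2, which read 2.91 to 3.43 in embryoid bodies, where these controls read 2.61 to 3.66.

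By limma 7593 genes were called in vector samples, 2946 higher and 4647 lower, and 7688 in samples labelled Bmi1, 2750 higher and 4938 lower. The balance between rises and falls depended on the scaling, since the median change over all genes was -0.24 and -0.27 as deposited, -0.04 and -0.03 after quantile normalization and -0.56 and -0.62 after centring each array on its median. After quantile normalization 3245 genes rose and 3425 fell in vector samples and 3118 and 3475 in samples labelled Bmi1, and after centring 2201 and 6058, and 1885 and 6372.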

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

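All tests of explanations in this part were chosen after the results were seen, while the test of the difference between the 2 effects was fixed before the data were examined. By that test (camera with a preset correlation), 9 gene lists differed between the effect in embryoid bodies and the effect in ES cells, each given as the median over members of the first effect minus the second. The differences were 1.51 for interferon response (adjusted p = 3e-18), -0.84 for endothelial (1.3e-08), 0.77 for cardiac muscle (5.2e-05), 0.69 for trophoblast (5.8e-04), -0.62 for imprinted (5.8e-04), -0.25 for Hox (0.012), -0.39 for erythroid (0.012), -0.62 for neuroectoderm (0.017) and -0.41 for endoderm (0.04). With an estimated correlation the interferon and endothelial lists held, both at adjusted p = 0.027, and the other 7 did not, with adjusted p between 0.094 and 0.47. With the embryoid body set as a block and an estimated correlation together none held, and both of these were at adjusted p = 0.18.

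Array control probe sets outside the comparisons were read too. The control probe sets for the transferrin receptor read 8.15 and 8.14 log2 units in embryoid bodies labelled Bmi1 against 6.18 and 7.45 in vector embryoid bodies, a difference of 1.33, and read the same gene as Tfrc, at 1.30 in the main comparison, so they are no separate finding. The 18S ribosomal RNA control probe sets were higher in ES cells than in embryoid bodies by 6.13 log2 units on average, with 13.25 to 14.02 on the ES cell arrays and 6.23 to 8.70 on the embryoid body arrays.

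Bmi1 signal was lower in the arrays labelled Bmi1 at both stages. Scaling between arrays is argued against by the distributions, since arrays of 1 set differed by at most 0.0323 log2 units in the mean over sorted values. After quantile normalization the difference was -1.69 in embryoid bodies and -1.42 in ES cells, each over 2 SE below 0. With distributions so alike within a set, that step could change little and is no separate test. An exchange of the group labels stays open: Cdkn2a, which Bmi1 is known to repress, was lower in the ES cells labelled Bmi1, at -1.19, and Cdkn2a and Cdkn2b were lower in embryoid bodies labelled Bmi1, at -0.39 and -0.70, which goes against an exchange but rests on 2 genes, of which none passed without the block. Cdkn2a was also dim, with a mean of 4.75 log2 units over the 8 arrays, where the array medians were 5.57 to 5.98. Bmi1 was also lower than in the untreated ES cells, so an exchange there would have to include that array. Probe sets outside the transduced cDNA that read the cell's own transcript also stay open, since both probe sets fell by amounts only 0.076 apart in embryoid bodies, while the probes' positions are not given in the sources used here. These 2 explanations cannot be told apart with these arrays, and no biological explanation was tested.

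Interferon response genes were higher in embryoid bodies labelled Bmi1. An origin in 1 embryoid body set is argued against by a median of 0.96 in the set where it was lower, with 16 of 16 members higher in both sets. More blood or macrophage cells are argued against in the replicate 1 arrays, where the interferon median was 1.5. There the macrophage and granulocyte median was -0.998, with 14 of 14 members lower. The general blood cell median was -0.91 there, with 17 of 19 members lower. In the replicate 2 arrays these medians were 0.36 and 0.32, so this explanation stays open for that set. Each set compares 1 array with 1 array. Over all 4 arrays the macrophage and granulocyte median was -0.38, without a call. A response of like size carried over from the ES cells is argued against by a median of -0.061 there against 1.39 in embryoid bodies, a gap of 1.45, more than 2 SD, with an SD of 0.591 between the members in ES cells. This argument is limited, because the list also read higher in vector embryoid bodies than in control ES cells, by a median of 2.49. Of its 16 members 12 were called higher and 2 lower there. With a lower signal in ES cells, a response may show less in them. A response that arose during embryoid body formation with the vector labelled Bmi1 may fit as a hypothesis, as may a difference between cultures unrelated to Bmi1, which 2 arrays per group do not test.

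Trophoblast genes were higher and endothelial genes lower in embryoid bodies labelled Bmi1 by camera with a preset correlation. With an estimated correlation the endothelial list held, adjusted p = 0.016, and the trophoblast list did not, adjusted p = 0.12. Scaling between arrays is argued against here too by the like distributions of labelled Bmi1 and vector arrays within each set. The trophoblast mean was 1.42 after quantile normalization and the endothelial list stayed lower, but that step could change little and is no separate test. An origin in a single embryoid body set is argued against for both lists. The trophoblast median was 0.67 in the set where it was lower, and endothelial medians were below 0 in both sets. A larger share of 1 cell type that lowers all others alike stays open. The cardiac muscle list had 13 of 20 members higher and 7 lower, with Pln at 1.80 and called, and Gata4 at -1.04. By camera with an estimated correlation it was not called, adjusted p = 0.32. That test called no list between stages, although it called the endothelial list here. The lack of a call for the cardiac list therefore does not decide this. A shift in the mix of cell types that embryoid bodies form may underlie the pattern, as a hypothesis that these data raise and that the label on Bmi1 leaves without a settled direction.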

How the results depend on the processing

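The count of called genes in embryoid bodies, 18, was 2 with the 75th percentile filter, 7 over every probe set, 6 after median centring, 3 with intensity trend and robust prior, 0 with array weights and 0 with arrays of the 1 stage only. It was 61 with the replicate block over the 6 numbered arrays, 271 with the block of the 2 embryoid body sets, and 0 to 218 over the leave-one-out fits. In ES cells the count of 6 was 0 over every probe set, 3 with the mean of probe sets, 0 after quantile normalization, 641 with array weights, 30 with the numbered replicate block, 216 with the embryoid body set block, 0 against either control array alone, 139 with arrays of the 1 stage only, and 0 to 50 without 1 array. The difference of the 2 effects, 0 genes, gave 1 with the mean of probe sets, 107 with the embryoid body set block and 0 to 100 without 1 array. The stage counts of 7593 and 7688 were 17734 and 17992 over every probe set, since more features were tested, and 5241 to 8284 and 5236 to 8496 without 1 array. All other settings stayed within 1.5 times. Where settings moved counts, the cause was not tested. Bmi1 stayed lower in every setting, between -2.02 and -0.996 in embryoid bodies and -1.89 and -1.29 in ES cells without 1 array. The numbered replicate block gave -1.51 with adjusted p = 0.048 in embryoid bodies and -1.59 with 0.054 in ES cells, the embryoid body set block 0.04 and 0.041, and array weights 0.0073 in ES cells.

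The number of lists called was 8 of 20 in embryoid bodies and 2 in ES cells. It was 2 and 0 with an estimated correlation, 4 and 1 by fry, 4 to 14 in embryoid bodies without 1 array and 1 to 2 in ES cells. The direction of a list is that of its test. Camera judges it relative to all other genes, so it can reverse while the mean of its members, given here, keeps its sign. Fry makes no comparison with other genes, so its direction can differ from that of camera for the same values. Among lists that were not called, the direction reversed in embryoid bodies for megakaryocyte and mast cell genes after quantile normalization (0.0182) and by fry (0.0098). In ES cells it reversed for endothelial genes after quantile normalization (0.0236) and with the embryoid body set block (0.0285), for hypoxia genes after quantile normalization (0.0662), and by fry for general blood cell (0.0232) and megakaryocyte genes (0.0254). Without 1 array the direction also reversed for several lists, none called in the main analysis, whose means in embryoid bodies ran from -1.07 to 0.836 for pluripotency, -0.321 to -0.159 for early mesoderm, -0.889 to 0.468 for general blood cell, -1.14 to 0.642 for macrophage and granulocyte, -0.263 to 0.282 for megakaryocyte and mast cell, -0.534 to 0.316 for mesenchyme, -0.165 to 0.162 for Polycomb, -0.451 to 0.145 for cell cycle inhibitors, -0.202 to 0.234 for proliferation, -0.098 to -0.0303 for imprinted and -0.272 to -0.0493 for hypoxia genes. In ES cells they ran from -0.0091 to 0.0686 for blood transcription factors, 0.02 to 0.0985 for erythroid, -0.0112 to 0.0682 for endothelial and -0.0187 to 0.191 for hypoxia genes. Opposite directions came from leaving out vector replicate 1 or 2 in embryoid bodies for 4 lists, in fits that mix in the difference between the sets. The medians of these lists within the sets also had opposite signs, so these arrays give them no direction. Without replicate 1 pluripotency genes were lower and mesenchyme, general blood cell and macrophage genes higher. Without replicate 2 pluripotency genes were higher and mesenchyme, general blood cell and macrophage genes lower. Of the 57 genes named for embryoid bodies 11 moved by over 1.5 times in some fit without 1 array, and 1 of 35 named for ES cells, and none changed sign.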

Other observations

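The 2 control ES cell arrays could be compared only as single arrays, without a test. Of 12982 genes, 18 read over 2-fold higher and 19 over 2-fold lower in the empty vector than in the untreated array, and Bmi1 differed by 0.33 log2 units. Among the replicates, 1453 genes lay over 2-fold apart in vector embryoid bodies, 598 in embryoid bodies labelled Bmi1 and 100 in ES cells labelled Bmi1.

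Polycomb genes other than Bmi1 showed few differences. In embryoid bodies labelled Bmi1, Pcgf5, a relative of Bmi1 in variant Polycomb complexes, was at 0.95 ± 0.20 (SE, n = 2 and 2 arrays), with limma adjusted p = 0.23 and 0.051 with the block, and Ezh1, a histone methyltransferase, was at 0.63 ± 0.16 and passed with the block at 0.045, although its 3 dimmer probe sets were at -0.135, 0.06 and -0.32. In ES cells labelled Bmi1, Yaf2 was at 1.04 ± 0.22 and passed with the block at 0.046. The smooth muscle genes Acta2 and Cnn1 were at 1.04 ± 0.25 and 1.13 ± 0.27 in the same cells, and neither passed.

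With the block, Gbp2, H2-Bl, Batf3, Marveld3, Med12l, Morc4 and Rhox5 were the 7 genes called higher at both stages in samples labelled Bmi1, and Sox18, Ttn and AI504432 were called in opposite directions. All were singled out after their values were seen. Sox18, an endothelial transcription factor, was at -0.88 in embryoid bodies and 0.91 in ES cells. Without 1 array it ran from -1.19 to -0.56 and from 0.80 to 1.02.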
